A study of Homo sapiens with 6 samples.

How the data were processed

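The series held 6 arrays of U87MG cells, an established human glioblastoma line grown in serum-containing medium. Per the labels, 3 arrays carried RNA of cells that were not irradiated and 3 carried RNA of cells given 1, 2 or 3 daily fractions of 2 Gy, which add up to 2, 4 and 6 Gy. Total RNA was extracted with Trizol and turned into biotin-labelled cRNA for an Illumina whole-genome expression BeadChip, per the labels' protocols. The deposited table gave 1 intensity on a linear scale for each gene symbol and array, and many of its cells were blank. GenomeStudio is named in the submitters' processing notes without a version. The background correction, the normalization, the rule that left cells blank and the way probes were combined into 1 value per gene are not given in the sources used here.

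The table had 34595 rows. Of these, 9119 had a value on all 6 arrays, 21230 had none and 4246 had values on some arrays. The arrays without irradiation had values for 10662, 10796 and 11160 genes, and those with 1, 2 and 3 fractions for 10986, 10741 and 11264. The lowest value on an array lay between 74.2 and 75.2 and the highest between 36324 and 44228. Over the genes with a value on every array, between 2.86% and 4.46% of an array's values were under 100. Most partly blank rows were dim: the median of their highest value was 97.6, and 3805 of 4246 stayed under the median of every array. But 308, or 7.25%, had a value above the median of every array over complete genes, so a blank does not always mark a low level. Blanks were therefore treated as missing, and the tests used the genes with a value on every array. Detection p-values and bead counts were not used here, so the precision of a value is known only from the number of arrays.

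Symbols in the table are those of the array's design. They were matched to current names in the RefSeq gene table of GRCh38.p14, which served for names only. Of the tested genes, 6399 matched by symbol and 1040 by a synonym that belongs to 1 gene, while 1680 kept the name in the table. The files name no genome build, so no coordinates are given. Families of near-identical genes, such as the HSPA1, HLA, histone, U3 and ribosomal protein genes, can share signal on a probe, and their members are reported as the table names them.

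Intensities were used as log2 values. The rule fixed before the data were examined kept values as deposited where the arrays' log2 medians lay within 0.1 of each other and called for quantile normalization otherwise. Over the genes with a value on every array the medians spanned 0.08, so values were kept as deposited. Over all values they spanned 0.16, because different genes were blank on each array, and quantile normalization was run as an alternative. No filter on dim genes was applied. As the table has 1 row per gene, the alternatives on the choice among probes could not be run.

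The series' design text states that each irradiated culture had a control kept for the same period. The numbers 1 to 3 in the control titles were taken to be those of these controls, which is an assumption. The matched number was a block in the fits, and a fit without it was an alternative. Deviations from the group means correlated across genes at -0.03, 0.07 and 0.10 between arrays of the same number, and between -0.11 and 0.06 between arrays of different numbers, so the pairing rests on the design text. Arrays of the same number had nearly the same sorted values, with mean absolute log2 differences of 0.01, 0.01 and 0.01, against 0.03 to 0.06 for other pairs of arrays. Arrays of 1 pair may thus have been scaled together, and levels set across pairs then compare arrays scaled separately. No 2 columns were identical.

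Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the prior variance on the mean level). 3 models were fitted to all 6 arrays, each with the matched number as a block: irradiation as a factor, cumulative dose in Gy as a number, and irradiation with its interaction with the number of fractions. The last leaves 1 residual degree of freedom and rests mainly on the prior. The Benjamini-Hochberg adjusted p had to be under 0.05. Differences are given as log2 ± the SE of limma over 3 pairs, and the pairs differ in dose and time, so the SE holds both. Its variance is drawn towards the prior shared between genes, so it can be smaller than the SE of a gene's own 3 differences. Nothing in the labels says that the cultures were repeated, so p-values rest on the spread between these arrays and on that prior.

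21 gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, a test of whether a list's genes move one way on balance, were alternatives. Each schedule had 1 array, so single schedules were described without a test: by counts of genes past 1.5-fold and 2-fold, and by the percentile of a list's median among 10000 random lists of the same size matched on mean level in 20 bins. Named genes followed a rule fixed before the data were examined. It took the 10 highest rises and 10 deepest falls in the irradiation test that shared their sign in all 3 pairs, and 5 and 5 for the dose trend. For each single schedule it took the 5 highest and 5 lowest differences among genes above the median level. For each list it took the 2 to 4 members of smallest unadjusted p, and it always took CDKN1A, MDM2, CCNB1 and MKI67. Symbols without a match to a current name stay unnamed under this rule, whatever their rank. Genes named outside this rule are said to be so.

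On simulated arrays with 9119 genes, of which 100 were shifted by 0.5 and 100 by 1 on the log2 scale, the irradiation test called 13% and 54% of the shifted genes and 1 of 8919 unshifted ones. The dose trend called 33% and 75%, with 2 of 8919 unshifted genes. The interaction called 0% at either size and 0 of 8919 unshifted genes. Other settings tried were a fit without the block, quantile normalization, median centring, filters on dim genes, other variance priors, an offset of 16 before the logarithm, a paired test per gene without a shared prior, each pair left out in turn and the mean of the 3 controls in place of the matched one. Settings added after the data had been seen were genes with values in at least 2 complete pairs, control 2 left out, and the hypoxia list median as a covariate. Plots were drawn with matplotlib 3.10.9.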

Results

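Gene expression was measured in U87MG glioblastoma cells after fractionated irradiation and in cells kept for the same periods without it. The kind of radiation and the time from the last fraction to RNA extraction are not given in the sources used here. The irradiated cultures received 2 Gy once a day for 1, 2 or 3 days, with 1 array per schedule and 1 non-irradiated array matched to each. The comparisons ask how expression changed after irradiation, whether the change followed the cumulative dose, and how the schedules resembled each other. The first principal component held 62.4% of the variance over 9119 genes and parted the groups: the non-irradiated arrays lay at -13.6, -18.5 and -7.65, and those with 1, 2 and 3 fractions at 5.83, 13.4 and 20.5.

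Irradiated cells had higher levels of most measured inflammatory cytokine genes and lower levels of most measured mitosis genes than their matched controls, and the early response genes FOS, EGR1 and FOSB were lower. PI3, which encodes the elastase inhibitor elafin, rose most, by a log2 difference of 2.95 ± 0.16 (SE, 3 pairs; limma adjusted p = 7.33e-10), or 7.72-fold. Its intensity was 248, 305 and 359 on the non-irradiated arrays and 1276, 2437 and 4004 after 1, 2 and 3 fractions. The cytokine IL6 rose by 2.69 ± 0.20 (adjusted p = 7.37e-08) and PTGS2, the inducible cyclooxygenase, by 2.57 ± 0.18 (adjusted p = 5.46e-08). FOS, a subunit of the AP-1 transcription factor, showed the deepest fall, with a difference of -2.87 ± 0.16 (adjusted p = 7.33e-10), or 0.136 of the control level.

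**Figure D1:**
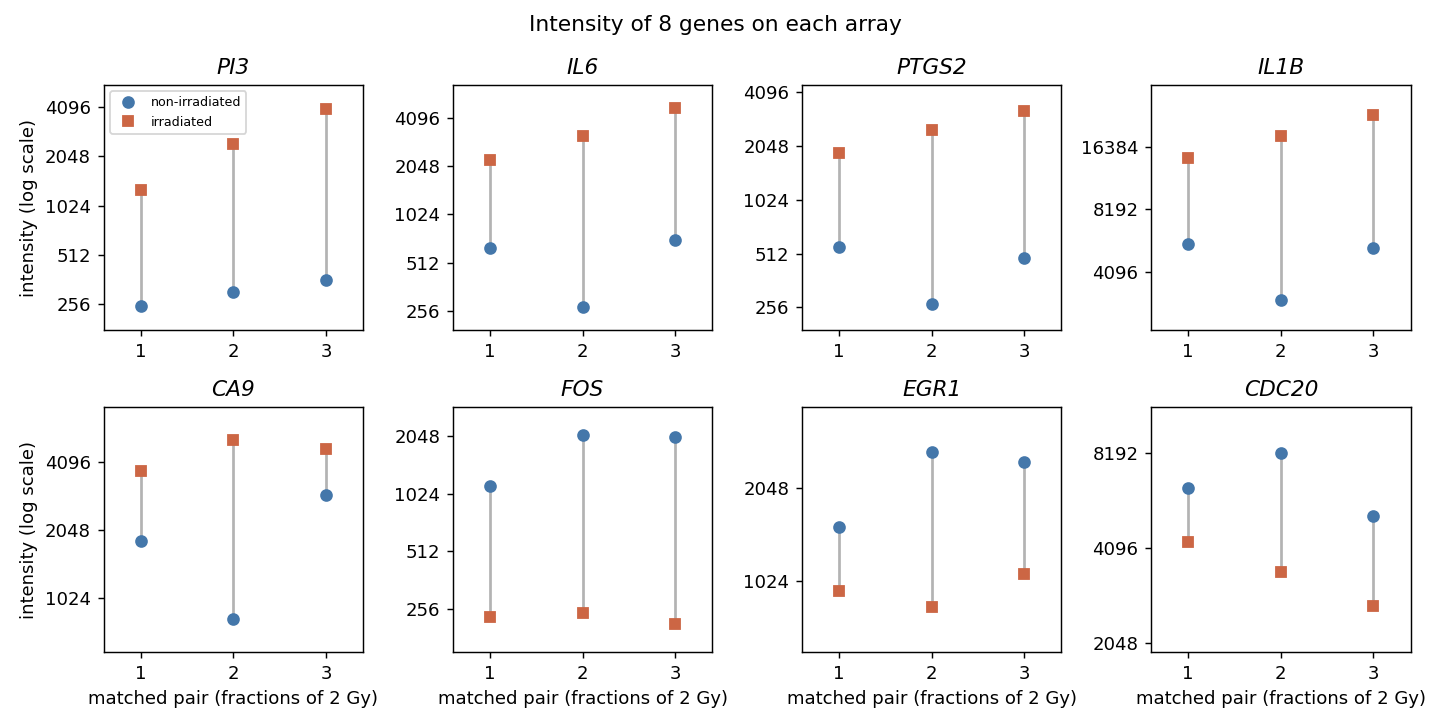
Intensity (log scale) of 8 genes on each of the 6 arrays, by matched pair, where the pair number is also the number of 2 Gy fractions; circles are non-irradiated arrays, squares irradiated ones, and a grey line joins the arrays of a pair. PI3, IL6, PTGS2, IL1B and CA9 lay higher on every irradiated array than on its matched control, and FOS, EGR1 and CDC20 lay lower.

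Of 9119 genes tested, 790 rose and 836 fell with irradiation, 17.8% in all, and 1600 of these 1626 had the same sign in all 3 pairs. Past 2-fold, 42 genes were higher and 6 lower; past 1.5-fold, 237 were higher and 148 lower. Among genes matched to a current name, the other leading rises were IL1B at 2.04 ± 0.16, LIF at 1.90 ± 0.14, IL1A at 1.66 ± 0.15, IGFBP3 at 1.51 ± 0.25, IL11 at 1.504 ± 0.12, CA12 at 1.48 ± 0.16 and CA9 at 1.45 ± 0.23. IL1A and IL1B encode interleukin-1 cytokines, and LIF and IL11 encode cytokines of the IL-6 family. CA9 and CA12 encode carbonic anhydrases induced by low oxygen. The other leading falls among such genes were CCN2 (CTGF in the table), a matrix-associated growth factor, at -1.32 ± 0.15, the early response factor EGR1 at -1.19 ± 0.15 and the HLH inhibitor ID3 at -1.11 ± 0.18. The unmatched symbols LOC100134073 at -1.03 and LOC648000 at -1.00021, given here after their values were seen, lay between ID3 and the next matched genes. These were the chaperone HSPA8 at -0.93 ± 0.12, the mitotic activator CDC20 at -0.93 ± 0.13 and FOSB at -0.92 ± 0.15. The mitochondrial ADP/ATP carrier SLC25A5 at -0.88 ± 0.12, the mitotic kinesin KIF20A at -0.87 ± 0.12 and the pyrophosphatase PPA1 at -0.87 ± 0.14 came next. The largest adjusted p among these 20 genes was 0.000531. The number of calls depended on pair 2: 601 genes were called without it, against 1626 with it, and with pair 3 left out, 488 genes fell, against 836. With a robust prior IGFBP3 (adjusted p = 0.261) and CA9 (0.231) lost their calls. The count also depended on sharing the spread between genes, since a paired test per gene without a shared prior called 0 genes, with 1557 at an unadjusted p under 0.05.

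Genes of mitosis fell together. Of 54 measured members of the G2/M and mitosis list, 49 fell, 0 rose and 5 did not pass, and 51 fell when adjusted over the list alone. The median difference was -0.59. Besides CDC20 and KIF20A, the spindle checkpoint kinase BUB1 fell by 0.85 ± 0.13 and the mitotic kinase PBK by 0.79 ± 0.12. Cyclin B1 (CCNB1) was at -0.65 ± 0.12 and the proliferation marker MKI67 at -0.54 ± 0.10, with adjusted p of 0.000949 and 0.000880. Of 42 genes of G1/S and DNA replication, 30 fell and 0 rose (35 fell when adjusted over the list alone), with a median of -0.44. TYMS, the thymidylate synthase, was at -0.73 ± 0.13, the flap endonuclease FEN1 at -0.72 ± 0.13, ATAD2 at -0.59 ± 0.11 and the origin recognition subunit ORC1 at -0.49 ± 0.09. Camera gave these lists adjusted p of 8.26e-30 and 1.31e-15; with an estimated correlation the adjusted p was 0.320 for both. The same lists also differed between non-irradiated arrays: control 3 minus control 2 gave a median of -0.35 for mitosis and -0.23 for replication. Control 2 minus control 1 gave 0.12 and 0.06, and control 3 minus control 1 gave -0.25 and -0.18.

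The list of genes for repair of DNA double-strand breaks had a lower median. Of 22 measured, 10 fell, 0 rose and 12 did not pass; adjusted over the list alone, 12 fell and 1 rose. The median was -0.29 (camera adjusted p = 8.17e-05, or 0.320 with an estimated correlation). Control 3 minus control 2 gave a median of nearly that size, -0.25. Control 2 minus control 1 gave 0.09 and control 3 minus control 1 gave -0.16. PARP1, which binds DNA breaks, was at -0.82 ± 0.12, the end-joining polymerase POLQ at -0.61 ± 0.12, the Ku subunit XRCC5 at -0.46 ± 0.10 and BARD1, the partner of BRCA1, at -0.50 ± 0.12, a call lost without pair 2 (adjusted p = 0.0629). The histone list held 13 measured genes, of which 1 rose and 2 fell, with the same counts when adjusted over the list alone and no shift of the list (camera adjusted p = 0.846). H4C3 was at -0.72 ± 0.13 and H1-2 at -0.40 ± 0.13, a call lost without pair 2 (adjusted p = 0.214) or pair 3 (0.107). H4C12 was at 0.28 ± 0.12 and did not pass (adjusted p = 0.108), and it is not the 1 gene that rose past the threshold, which is not named here.

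Inflammatory cytokines and NF-kB targets formed the list with the highest median, 0.89. Of 24 measured members 19 rose, 1 fell and 4 did not pass, and 20 rose and 1 fell when adjusted over the list alone. Of the 42 genes higher past 2-fold, 10 belonged to this list. LIF, PTGS2, IL6 and IL11 had its smallest p-values. Camera gave an adjusted p of 1.28e-18, and the adjusted p was 0.320 with an estimated correlation. For this list control 3 minus control 2 gave a median difference over genes of 0.46. Control 2 minus control 1 gave -0.33 and control 3 minus control 1 gave 0.0031.

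Many genes of the hypoxia and glycolysis list rose. Of 30 measured, 18 rose, 1 fell and 11 did not pass (20 rose and 1 fell when adjusted over the list alone), with a median of 0.58. CA12 rose most; the hormone gene STC1 rose by 1.42 ± 0.16, the lipid-droplet gene HILPDA by 1.34 ± 0.20 and ANGPTL4 by 0.92 ± 0.13. HILPDA lost its call with a robust prior (adjusted p = 0.103). Camera gave an adjusted p of 2.30e-12, and the adjusted p was 0.39998 with an estimated correlation. By schedule the list median was 0.34, 1.07 and 0.31 after 1, 2 and 3 fractions. Among the non-irradiated arrays alone, control 3 minus control 2 gave a median difference over the list's genes of 0.65. Control 2 minus control 1 gave -0.38 and control 3 minus control 1 gave 0.21.

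The p53 target list had a slightly higher median. Of 20 measured members, 5 rose, 1 fell and 14 did not pass; adjusted over the list alone, 7 rose and 1 fell. The median was 0.20, with a camera adjusted p of 0.0332, and the adjusted p was 0.39998 with an estimated correlation. The call was lost without pair 1 (adjusted p = 0.0591) and without pair 3 (adjusted p = 0.142). GDF15, a stress cytokine, rose by 1.08 ± 0.12, SUSD6 by 0.64 ± 0.12 and the stress sensor SESN2 by 0.44 ± 0.12, while TIGAR was at -0.35 ± 0.09. SESN2 lost its call without pair 2 (adjusted p = 0.0732) or pair 3 (0.0704), and TIGAR without pair 2 (0.133). GDF15 and SESN2 are also known to respond to ATF4. The cell-cycle inhibitor CDKN1A had a value on 1 array only, 3227 on non-irradiated array 3. MDM2, and FDXR and TP53I3, which are named outside the rule, were blank on every array. These targets of p53 could therefore not be compared.

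Ribosomal protein genes had a lower median, and few respiratory genes passed. Of 71 cytosolic ribosomal protein genes, 30 fell, 0 rose and 41 did not pass (44 fell when adjusted over the list alone). Their median was -0.32. RPL29 was at -0.78 ± 0.11, RPS2 at -0.71 ± 0.13 and RPS7 at -0.66 ± 0.12. Of 67 oxidative phosphorylation genes, 8 fell, 0 rose and 59 did not pass, and 3 fell when adjusted over the list alone. The complex III subunit UQCRFS1 was at -0.69 ± 0.12, ATP5PB at -0.55 ± 0.12, SDHB at -0.50 ± 0.13 and UQCRB at -0.34 ± 0.10. UQCRB lost its call without pair 2 (adjusted p = 0.158) or pair 3 (0.140), and SDHB without pair 3 (0.126). Camera adjusted p were 3.28e-15 and 4.93e-05, and adjusted p were 0.320 and 0.522 with an estimated correlation. Control 3 minus control 2 gave medians of -0.12 for the ribosomal list and 0.01 for the respiratory list. Control 2 minus control 1 gave 0.07 and -0.02, and control 3 minus control 1 gave -0.09 and 0.000634.

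Smaller positive medians passed camera for 3 further lists. In the unfolded protein and ATF4 response list 11 of 36 rose and 1 fell (15 and 1 when adjusted over the list alone), with a median of 0.26. Its leading members were the stress factor NUPR1 at 0.80 ± 0.12, ASNS, the asparagine synthetase, at 0.55 ± 0.12, DDIT3 at 0.52 ± 0.12 and CHAC1 at 0.49 ± 0.09. In the extracellular matrix list 5 of 24 rose and 1 fell (9 and 2 when adjusted over the list alone), with a median of 0.23. The collagen gene COL6A1 rose by 1.13 ± 0.13, PLOD1 by 0.66 ± 0.12 and TIMP1 by 0.56 ± 0.11, and the protease gene ADAMTS1 was at -0.59 ± 0.11. In the lysosome and autophagy list 7 of 31 rose and 1 fell (11 and 1 when adjusted over the list alone), with a median of 0.18; WIPI1 rose by 0.67 ± 0.14, GABARAPL1 by 0.63 ± 0.12, GAA by 0.55 ± 0.09 and CTSZ by 0.41 ± 0.10. Camera adjusted p were 0.000397, 0.000769 and 0.000769; with an estimated correlation the adjusted p were 0.320, 0.39998 and 0.320. Between controls, array 3 minus array 2 gave medians of 0.14, 0.26 and 0.04 for these lists. Array 2 minus array 1 gave -0.09, -0.13 and -0.08, and array 3 minus array 1 gave 0.05, 0.05 and -0.09. The matrix list thus differed by more between controls 3 and 2 than with irradiation, and by less between the other controls. Without pair 2 the matrix list lost its call (adjusted p = 0.0531), and so did ASNS (0.0586), DDIT3 (0.0527), WIPI1 (0.0728) and CTSZ (0.0944).

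The remaining 9 lists after the histones did not pass camera, although single members did. In the type I interferon list 3 of 37 rose and 1 fell: ISG20 was at 0.67 ± 0.12, STAT2 at 0.37 ± 0.12, MX1 at 0.36 ± 0.09 and IFI44L at -0.38 ± 0.12. In the TGF-beta list 5 of 24 rose and 3 fell, among them LOX at 0.98 ± 0.16 against CCN2 and ID3. In the MHC list 4 of 21 rose and 0 fell, with HLA-B at 0.81 ± 0.12, HLA-F at 0.46 ± 0.12 and HLA-G at 0.41 ± 0.11. In the heat shock list HSPA1B rose by 1.20 ± 0.16, HSPA8 and the chaperonin HSPE1 (-0.44 ± 0.12) fell, and HSPD1 at -0.30 ± 0.12 did not pass. In the NRF2 list 2 of 22 rose and 5 fell, with HMOX1 at 0.76 ± 0.12 and the peroxiredoxin PRDX3 at -0.63 ± 0.12, AKR1B10 at -0.45 ± 0.09 and TKT at -0.48 ± 0.12. In the cholesterol list 2 of 22 rose and 3 fell, with INSIG1 at 0.61 ± 0.16, FASN at -0.47 ± 0.12 and PMVK at -0.32 ± 0.09. In the stem cell and glial list 2 of 9 rose, CEBPB at 0.36 ± 0.11 and ALDH1A3 at 0.42 ± 0.13, and BMI1 at -0.30 ± 0.12 and CD44 at 0.19 ± 0.11 did not pass. Adjusted over each list alone, the counts that rose and fell were 2 and 0 for interferon, 7 and 7 for TGF-beta, 5 and 0 for MHC, 1 and 2 for heat shock, 2 and 5 for NRF2, 2 and 3 for cholesterol and 2 and 0 for stem cell genes. Camera adjusted p were 0.192, 0.846, 0.0851, 0.468, 0.0672, 0.206 and 0.348 in that order.

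Many of these single calls were lost when 1 pair was left out, some at nearly the same size: without pair 2 FASN was at -0.46, INSIG1 at 0.60, CEBPB at 0.38 and STAT2 at 0.34. Without pair 2 the adjusted p was 0.153 for MX1, 0.235 for IFI44L, 0.181 for STAT2, 0.0772 for FASN, 0.0874 for INSIG1, 0.139 for PMVK and 0.152 for TKT. It was 0.115 for CEBPB, 0.235 for ALDH1A3 and 0.120 for HLA-G. Without pair 3 it was 0.113 for IFI44L, 0.161 for STAT2, 0.195 for INSIG1, 0.0669 for PMVK, 0.140 for CEBPB, 0.231 for ALDH1A3 and 0.0940 for HLA-G. Without pair 1, HSPE1 (0.142) and CEBPB (0.0592) lost their calls. The NRF2 list passed camera without pair 2 (adjusted p = 0.0220); over all pairs it did not pass, with an adjusted p = 0.39998 with an estimated correlation.

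Immediate early genes moved both ways. Of 28 measured, 7 rose, 8 fell and 13 did not pass (11 and 9 when adjusted over the list alone; camera adjusted p = 0.966). FOS, EGR1 and FOSB fell, and the survival gene IER3 rose by 1.04 ± 0.12. The list's median was 0.06, its mean was -0.08 and the direction camera gave was down, so these differ in sign. Among 5 measured markers of blood, endothelial, epithelial and neuronal cells, CD68 rose by 0.55 ± 0.12 (0 others passed), and it lost its call without pair 2 (adjusted p = 0.0532). SNAP25 was at 0.40 ± 0.14 and passed without pair 1 (adjusted p = 0.00770) or pair 3 (0.0257). GAD1 at -0.20 ± 0.11 and TEK at 0.08 ± 0.08 did not pass. Adjusted over the list alone, 2 rose and 0 fell (camera adjusted p = 0.366). CD68 is also a lysosomal gene that many tumour lines express.

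Calls of lists depended on how correlation between genes was treated. Camera called 11 of 21 lists between the groups, and it called between 8 and 11 lists in each of the 9 other splits of the 6 arrays into 3 and 3. With an estimated correlation 0 lists were called (3 at an unadjusted p under 0.05), and with fry 0 were called (11 at an unadjusted p under 0.05, smallest adjusted p = 0.0703). For single genes, the real split gave 1626 calls and the highest of the other splits 0, with 44 to 634 genes at an unadjusted p under 0.05. These splits are no measure of false calls: with the block, 6 of them compare irradiated with control in 1 pair, and 3 reverse the sign of 1 pair, so the effect of irradiation is in them too.

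**Figure D2:**
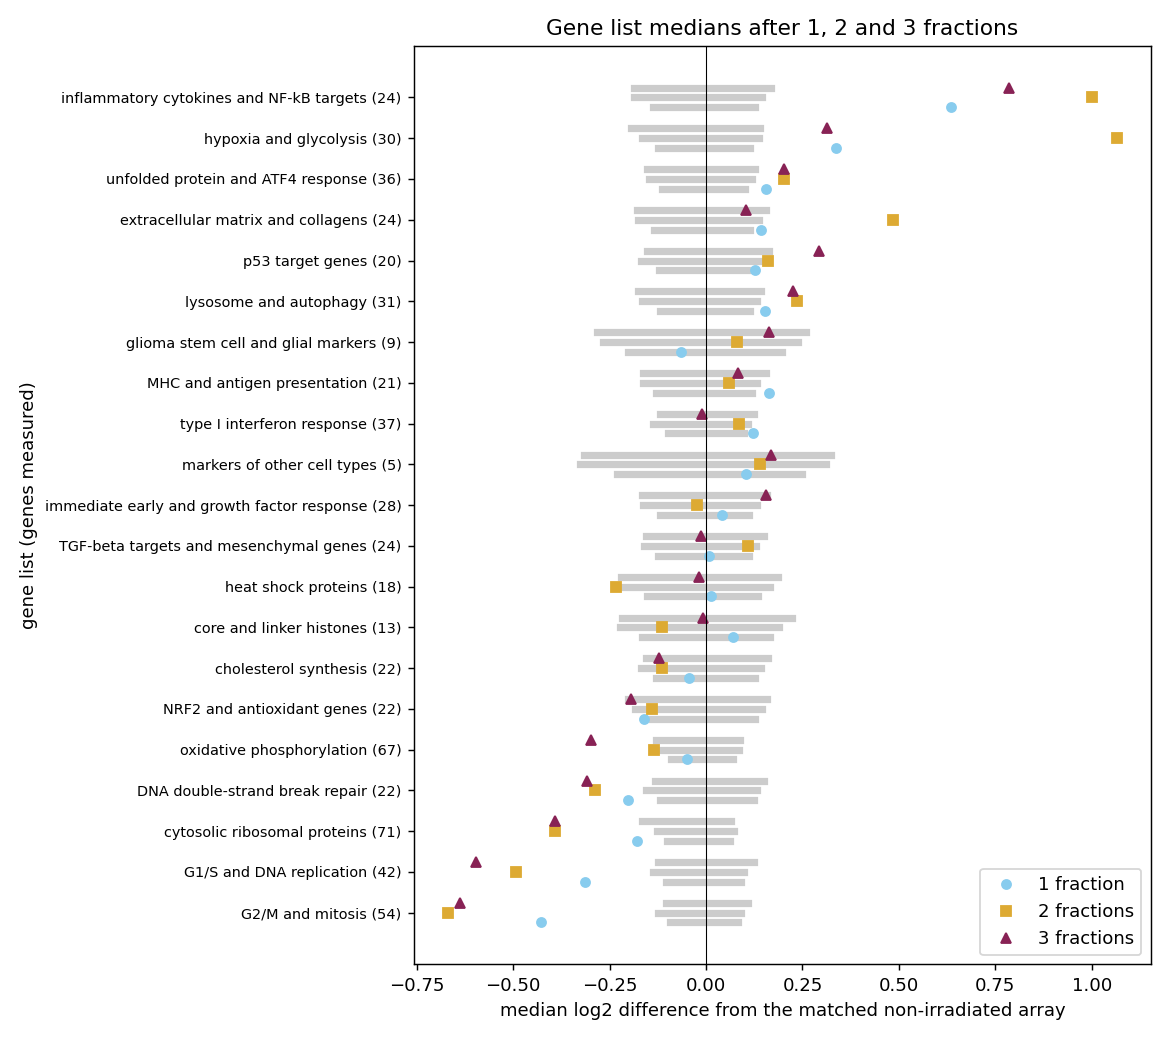
Median log2 difference of each of the 21 lists between the irradiated array and its matched non-irradiated array after 1, 2 and 3 fractions (points); grey bars span the central 95% of medians of 10000 random lists of the same size and mean level. The G2/M and mitosis medians of -0.43, -0.67 and -0.64 and the inflammatory medians of 0.636, 1.0007 and 0.784 lay outside the bars at every schedule. Genes of the random lists were drawn one by one, so the bars leave out correlation between the genes of a list and are no test. Between non-irradiated arrays, control 3 minus control 2 gave medians of -0.35 for mitosis and 0.46 for inflammatory genes, also beyond these bars.

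The dose trend fitted the change per Gy with the controls at 0. With it, 640 genes rose and 681 fell, 1321 in all, and 1186 of them were also called in the irradiation test, all with the same sign. Among genes matched to a current name, PI3 rose by 0.67 ± 0.05 per Gy (adjusted p = 2.03e-05), IL6 by 0.61 ± 0.06, PTGS2 by 0.59 ± 0.05, IL1B by 0.46 ± 0.05 and LIF by 0.43 ± 0.04. FOS was at -0.65 ± 0.05 per Gy, CCN2 at -0.32 ± 0.03, ID3 at -0.29 ± 0.03, EGR1 at -0.27 ± 0.04 and PPA1 at -0.21 ± 0.03. Of the mitosis list 49 of 54 members fell with dose and 0 rose, and of the inflammatory list 18 of 24 rose and 1 fell. As all controls lie at 0 Gy, this trend also takes up any difference between irradiated and control arrays that does not depend on dose. Cumulative dose rose together with the number of fractions and the days of treatment, so the trend cannot tell these apart. Levels set across pairs also compare arrays that may have been scaled separately. With pair 1 left out, 843 genes were called. Without the block, which rests on the assumed pairing, 1036 genes fell, against 681. With a robust prior the dose calls of IL6 (adjusted p = 0.123), PTGS2 (0.0737) and IL1B (0.0703) were lost.

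The interaction of irradiation with the number of fractions asks whether the difference from the matched control grew or shrank. It cannot tell fractions from cumulative dose or days of treatment either, as these rose together. The interaction called 10 genes, of which 3 grew higher and 7 lower, with 500 at an unadjusted p under 0.05. VTRNA2-1 (MIR886 in the table) was at -0.89 ± 0.16 per fraction, and its matched differences were 0.14, -0.54 and -1.64. ID3 was at -0.70 ± 0.16 per fraction, with differences of -0.33, -1.25 and -1.74. The count fell to 1 without the block, to 2 with quantile normalization or a prior without trend, and to 5 without the dimmer genes.

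Single schedules were set against their matched control without a test. After 1 fraction 23 genes were higher and 2 lower past 2-fold. After 2 fractions 129 were higher and 26 lower, and after 3 fractions 53 were higher and 29 lower. Between non-irradiated arrays 5, 0 and 16 genes lay past 2-fold. Among brighter genes matched to a current name, the highest differences after 1 fraction were PI3 at 2.36, IL6 at 1.82, PTGS2 at 1.76, IL11 at 1.51 and LIF at 1.503, and the lowest were FOS at -2.27, DOCK10 at -0.92, TYMS at -0.88, HNRNPR at -0.85 and PARP1 at -0.85. After 2 fractions IL6 stood at 3.53, PTGS2 at 3.24, PI3 at 2.998, IGFBP3 at 2.83 and DEPP1, a FOXO target, at 2.80. The lowest were FOS at -3.09, EGR1 at -1.68, FOSB at -1.49, CCN2 at -1.41 and CDC20 at -1.26. Of the rises, all but PI3 had their lowest control value on non-irradiated array 2: IL6 272, PTGS2 267, IGFBP3 516 and DEPP1 399. On the irradiated arrays IL6, PTGS2 and IGFBP3 were highest after 3 fractions, at 4670.5, 3205 and 3894, and DEPP1 after 2, at 2774. Such levels compare arrays that may have been scaled separately. With a robust prior DEPP1 lost its irradiation call (limma adjusted p = 0.342). After 3 fractions PI3 stood at 3.48, IL6 at 2.72, PTGS2 at 2.72, LIF at 2.13 and IL1B at 2.12, against FOS at -3.26, CCN2 at -1.78, ID3 at -1.74, VTRNA2-1 at -1.64 and PPA1 at -1.36. The order of the schedules by count depended on the control: against the mean of the 3 controls 30, 65 and 132 genes lay past 2-fold.

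**Figure D3:**
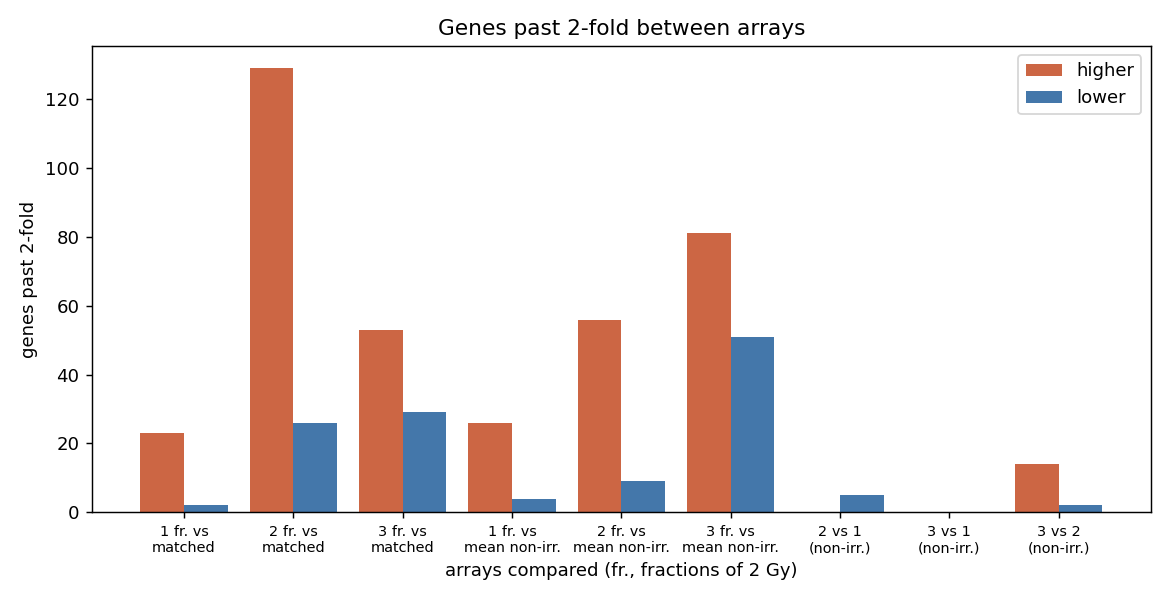
Number of genes past 2-fold higher (red) and lower (blue) for each schedule against its matched control, for each schedule against the mean of the 3 non-irradiated arrays, and between non-irradiated arrays. After 2 fractions 155 genes passed against the matched control and 65 against the mean of the controls, and between controls at most 16 passed.

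Matched differences of the schedules were correlated. Across genes, which are not independent replicates, matched differences correlated at r = 0.60 between 1 and 2 fractions, 0.56 between 1 and 3 and 0.64 between 2 and 3 (Spearman's rho 0.53, 0.50 and 0.58). These differences share no array. For comparison, the later minus the earlier of the other controls correlated with the matched difference at 0.32 for 1 fraction (control 3 minus 2), 0.24 for 2 fractions (3 minus 1) and -0.08 for 3 fractions (2 minus 1). Past 2-fold, 18, 14 and 39 genes were shared by the same pairs of schedules, all with the same sign, where independent lists would share 0.425, 0.225 and 1.39.

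**Figure D4:**
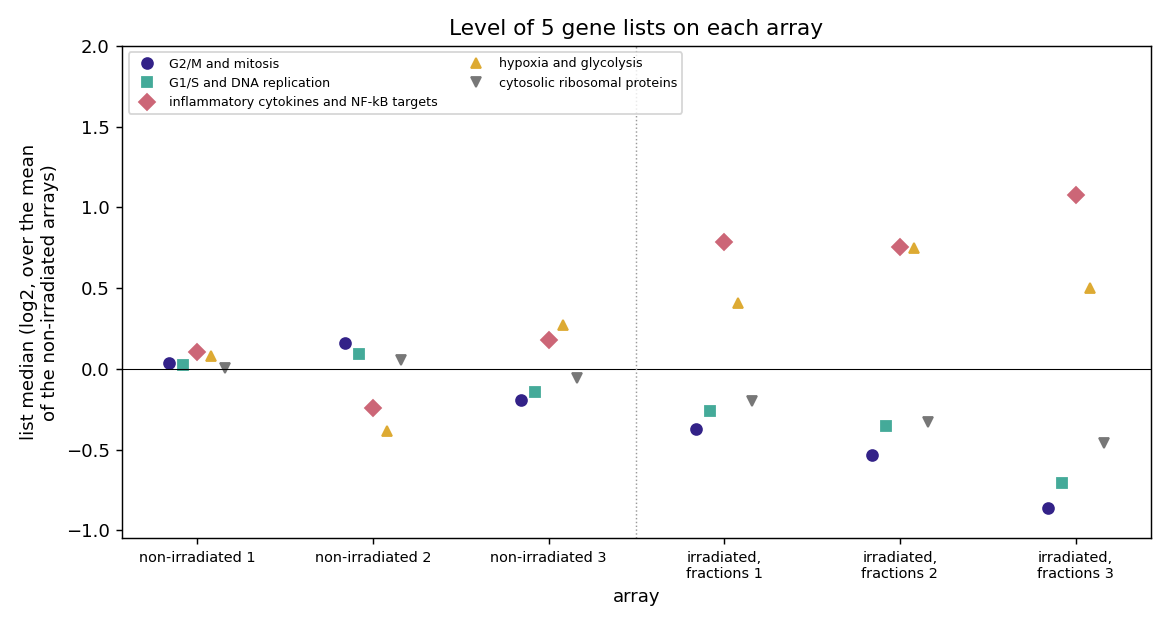
Median level of 5 gene lists on each array, as log2 over the mean of the non-irradiated arrays; each symbol is 1 list on 1 array. The hypoxia list lay at -0.38 on non-irradiated array 2 and at 0.41, 0.75 and 0.50 on the irradiated arrays, and the mitosis list at -0.37, -0.54 and -0.86 on the irradiated arrays.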

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

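Chosen only after the results had been seen were the test of control 2 and the test of the hypoxia response to 2 fractions, whose list medians were already known, and the SDs and SEs given for the second pattern. The hypoxia covariate used for the second pattern was also added after the data had been seen.

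In 10 genes the irradiation effect changed with the number of fractions in the limma interaction. The effect grew higher by 0.88 per fraction for SERPINB2, 0.70 for SLC16A6 and 0.62 for GJB2. It grew lower for VTRNA2-1 (-0.89), LOC653505 (-0.71), ID3 (-0.70), CCL2 (-0.65), NNMT (-0.62), S100A4 (-0.52) and LOC100134241 (-0.49). All but ID3 and VTRNA2-1 fall outside the rule for named genes. Part of such a change can lie in the controls. SERPINB2 was at 833.5, 455.5 and 420.6 on the controls and at 934.3, 916.2 and 1597.5 after 1, 2 and 3 fractions. VTRNA2-1 was at 306, 542 and 597 on the controls and at 338, 372 and 191 after irradiation. With 1 residual degree of freedom the test rests on the prior. On simulated arrays it called 0% of genes shifted by 1 per fraction. The noise of those arrays was set from the irradiation fit, so this share does not give the power of the test here.

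Genes with blank cells lie outside the tests. Values were present on all irradiated arrays and on no non-irradiated array for 73 genes, and the reverse held for 42. These add to 115, and the highest of the other 9 splits gave 84, so the count alone says little. Most were dim: the median of their highest value was 101.6, and 105 stayed under the median of every array. The brightest on each side, named after their values were seen, were exceptions. SLC25A51 had values of 4522, 4466 and 5490 on the irradiated arrays and blanks on the others, and BCL2L1 reached 1141 on the non-irradiated arrays and was blank on the others. The rule behind blanks is unknown, so no fold is given for them.

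The split of the 6 arrays by irradiation gave 1626 called genes, and the highest of the other splits gave 0; 1 of 10 splits gave as many, the real one included. For gene lists the real split gave 11 calls and the highest of the others 11, so that 2 of 10 splits gave as many. With 10 splits the share cannot go under 0.05. Of the other splits, 3 part all pairs and reverse 1 of them, and they gave 0 genes and 9, 8 and 11 lists; the other 6 compare irradiated with control in 1 pair. The effect of irradiation is thus in each of them.

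The first pattern weighed is the larger number of genes past 2-fold after 2 fractions, 155, than after 1 (25) or 3 (82). Scale of the arrays stays undecided: quantile normalization gave 149 against 85 after 3 fractions, but matched arrays already had nearly the same sorted values, so it could hardly move either count. A larger response of the hypoxia genes to 2 fractions stays open: on that array their level over the other irradiated arrays was 0.15 as a median of differences and 0.29 as a difference of medians, and control 2 was at -0.58 and -0.56 against the other controls. Against the mean of the 3 controls the count fell to 65, under the 132 after 3 fractions, which is consistent with a control of that pair that stands apart. Why that control differs, through its culture or its array, was not tested.

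The second pattern is the fall of mitosis genes with the rise of inflammatory genes. A candidate explanation is a culture state, followed by the hypoxia genes, that also differs between untreated dishes. Of 69 members called with the block, 66 were called without it, and with the hypoxia median as a covariate and no block 0 were (0%). The mitosis median moved from -0.61 (SD 0.14 over members) to -0.16 (SD 0.22), and the inflammatory one from 0.99 (SD 0.77) to 0.56 (SD 0.51). The calls ended both because effects shrank and because the median SE rose from 0.15 to 0.28, as the covariate follows irradiation, so this state and irradiation cannot be told apart here, and differences between controls correlated with matched differences at 0.32, 0.24 and -0.08.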

How the results depend on the processing

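Leaving out control 2, genes with 2 complete pairs and the hypoxia covariate were chosen after the data had been seen. Of 1127 values of named genes over the alternatives, 986 stayed on the same side of the threshold, 138 lost the call, 3 gained it and 0 reversed. Where neither value passed, a change of sign was not counted as a reversal. Of the lost calls, 90 were lost in the paired test without a shared prior, which kept no call. Leaving out pair 2 lost 23 and leaving out pair 3 lost 12, so the pooled share hides large differences between the alternatives. Without the replicate block 1350 genes were called for irradiation and 1852 for dose, 1036 of them lower, and 1 for the interaction (1 higher, 0 lower); it changed no call of a list. The interaction gave 2 calls with quantile normalization (1 higher, 1 lower) and 2 with a prior without trend (1 and 1). Leaving out genes under the median level gave 1035 calls for irradiation (470 higher), 393 higher for dose and 5 for the interaction (3 lower), as fewer genes were tested; leaving out those under the lower quartile gave 5 (3 lower). Between controls 1 and 3 0 genes lay past 2-fold, 1 with quantile normalization and 2 with median centring. With 1 pair left out in turn, irradiation gave 601 to 1694 calls (319 to 807 higher, 282 to 887 lower) and dose 843 to 1241 (406 to 660 higher, 437 to 581 lower), from fewer arrays. A paired test without a shared prior gave 0 calls for irradiation, 0 higher and 0 lower, with 1557 at an unadjusted p under 0.05. Camera with an estimated correlation and fry gave 0 lists (3 and 11 at an unadjusted p under 0.05). Without control 2 and without the block, irradiation gave 913 calls (473 higher, 440 lower). With the hypoxia covariate it gave 1 (0 higher, 1 lower). Apart from the loss of arrays and genes named, the cause was not tested. Against the mean of the 3 controls 65 and 132 genes lay past 2-fold after 2 and 3 fractions, and schedules correlated across genes at 0.782 (1 and 2), 0.818 (1 and 3) and 0.824 (2 and 3). Unchanged schedules simulated against shared controls gave 0.251 on average; the mean covariance was 0.0712 against 0.0074 simulated, and 0.0634 with matched controls. Genes with 2 complete pairs added 770 to the test, of which 44 rose and 15 fell. The planned choices among probes were not run, as the table has 1 row per gene. Arrays number 6, and signal over background was not used here, so dim genes near the lowest value are limited in an unknown way.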

Other observations

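Chosen only after the values had been seen were the test on histone genes and both tests on 6 small RNAs, with the choice of these 6, the brightness bound and the bound of 2 SDs.

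Of the 42 genes higher past 2-fold, 24 lie in no list fixed beforehand, and the genes named in this paragraph were chosen after their values were seen. The prostaglandin E synthase PTGES rose by 1.18 ± 0.12, next to PTGS2, which acts before it in the same pathway. The tissue factor gene F3 rose by 1.32 ± 0.18, the monocarboxylate transporter SLC16A6 by 1.43 ± 0.18 and DDIT4L by 1.15 ± 0.18. The growth-factor receptor regulator LRIG1 rose by 1.06 ± 0.14, the mitochondrial iron importer SLC25A37 by 1.03 ± 0.12 and the adenosine receptor ADORA2A by 1.02 ± 0.11. Each had the same sign in all 3 pairs.

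Small RNAs without poly(A) tails were sorted by name into classes. Of 78 measured, 10 rose and 9 fell, and the median was -0.03. Of 53 sorted as small nucleolar RNAs 7 rose and 7 fell, and of 12 sorted as U RNAs 0 rose and 0 fell. Sorting by name put SNORD139 (RNU86 in the table), a small nucleolar RNA by its current name, among the U RNAs. The third pattern weighed is the rise of 6 small RNAs past 1.5-fold, chosen after their values were seen: the 5S ribosomal RNA RNA5S9 at 1.39 ± 0.12, SNORD3A at 1.08 ± 0.12, the 7SK RNA RN7SK at 1.05 ± 0.12, SNORD3D at 1.02 ± 0.13, SNORD3C at 0.86 ± 0.12 and SNORA12 at 0.75 ± 0.11. The SNORD3 genes are near-identical copies of the U3 RNA.

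Scale of the arrays stays undecided for these 6: their median was 1.03 as deposited and 1.02 under the lower of quantile normalization and median centring, but matched arrays already had nearly the same sorted values, so neither could move it. More carry-over of RNA without poly(A) tails into the labelled material is argued against only as an equal rise of all such RNAs. The 8 bright U RNAs, which also lack such tails, had a median of 0.20 (SD 0.10). These U RNAs are 3 kinds only, 5 copies of U1, 2 of U6 and U4atac, with medians of 0.18, 0.23 and 0.00242. The 6 were picked from all classes for their rise, so a lower median of the U RNAs follows in part from that choice. Carry-over that differs between RNAs stays undecided. For small RNAs as a class both tests are void, because the class did not rise: the median was -0.032 under quantile normalization, and the histone genes that depend on replication had a median of -0.12 (SD 0.299). As first worded the rules for these 2 tests were met; the reading was changed to undecided after that was seen, since a median near 0 meets them whatever the cause. A change in these RNAs with irradiation may remain, as a hypothesis; a change in how they were labelled or extracted one by one was not tested.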
